A study of Homo sapiens with 4 samples.

How the data were processed

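Human coronary artery endothelial cells, bought as primary cells and used between passages 3 and 8, were grown for 14 days on a soft hydrogel of 4 kPa or on tissue culture plates (called TC), with or without transforming growth factor beta (TGF-β) at 20 ng/ml. Wells were seeded with 120000 cells, and the medium held 5% serum, per the labels' protocols. Each of the 4 conditions gave 1 droplet library (Chromium chemistry, version 3) aimed at 8000 cells, and the libraries were pooled on a NovaSeq flow cell. The groups are written 4kPa, 4kPa+TGFB, TC and TC+TGFB.

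The deposited files hold UMI counts, that is, whole numbers of distinct molecules per gene and cell barcode, which were used as given. Reads were processed with Cell Ranger, STAR and bcl2fastq on the GRCh38 genome, per the submitters' processing notes, which give Cell Ranger version 3.0, while the headers of the count matrices give software version 3.1.0. The authors had filtered barcodes down to called cells: the matrices hold 5368, 4347 and 7123 barcodes for 4kPa, 4kPa+TGFB and TC. For TC+TGFB only the list of 7150 barcodes was used, and its counts were not analysed here, so no effect of TGF-β on tissue culture plates and no interaction of TGF-β with stiffness was computed. The series gives 21644 cells over the 4 libraries after a filter on mitochondrial content and total counts whose limits are not given in the sources used here. The 4 barcode lists together hold 23988 entries.

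A barcode was kept with at least 2000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrial genes. This left 13571 cells in the 3 libraries: 4614 in 4kPa, 3374 in 4kPa+TGFB and 5583 in TC. Had the series kept every TC+TGFB barcode, it would have kept 14494 cells of these 3 libraries, so its limits were looser than those used here. Scrublet (through scanpy 1.11.5) called 0, 2 and 2 doublets in the 3 libraries. That is under the 0.5% below which the calls were taken as not working, so no doublets were removed and cell pairs stay in the data. XIST, TSIX and genes of chromosome Y (130 of the 33538 listed features) were left out of every table.

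UMIs were summed over the kept cells of a library and divided by the library's total to give scaled counts (CPM). The ratio of CPM between 2 libraries was given with its exact conditional binomial 95% interval, and a library's CPM with an exact Poisson interval. Both cover counting error only. With 1 library per condition there was no test and no p-value, since cells are not replicates. Genes at least 2-fold apart were counted among those with at least 10 CPM in either library. For 29 gene lists, members with at least 5 CPM were counted as at least 1.5-fold higher or lower, and the median log2 ratio was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins, as a description of these libraries. Medians were placed for lists with at least 5 measured members.

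The genes named were the 10 with the highest and the 10 with the lowest ratio among genes with at least 50 CPM, up to 4 members per list with the largest ratio among those with at least 20 CPM, and ACTA2, TAGLN, CNN1, PECAM1, CDH5, VWF and CTGF. Some genes that this rule or the other settings bring up are not reported here. Mitochondrial, ribosomal protein, clone-named and non-coding genes were left out of the first part of that rule. The rule, the lists, the cell limits and most other settings tried were set before the data were examined. Any other gene named was chosen after its values were seen.

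Shares of cells with a UMI were computed after drawing 5000 UMIs from each cell, with exact binomial (Clopper-Pearson) 95% intervals. This left out 134 cells of 4kPa, 244 of 4kPa+TGFB and 498 of TC that held fewer. Cells of the 3 libraries were clustered together from counts scaled to 10000 per cell and logged, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.5. Gene positions are from the GENCODE 29 annotation of GRCh38, matched on gene identifier. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

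The ratio and list code was tested on simulated counts with 200 genes altered by known folds. Both simulated libraries were Poisson draws from a shared profile, with no variation between cultures. The values below therefore check the code for counting error and give no rate of false 2-fold calls between cultures. For TC over 4kPa, with 8568 genes, the 95% intervals held the true ratio for 95.6% of genes, all 66 genes altered 4-fold were found at least 2-fold apart, and 0 of 8368 unaltered genes were. For 4kPa+TGFB over 4kPa, with 8603 genes, the intervals held the true ratio for 95.2%. Of genes altered exactly 2-fold, 61.2% and 55.2% in the respective comparisons passed the 2-fold limit.

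Other settings fixed beforehand were all deposited barcodes, limits at 3 median absolute deviations, at most 10% mitochondrial UMIs, doublet calls kept, median-of-ratios scaling, CPM without mitochondrial and ribosomal protein genes, equal weight for each cell, and only cells without UMIs of 6 cycling genes. Other limits on CPM, other thinning depths and other cluster resolutions were fixed beforehand too. Leaving out cells under 5000 UMIs and leaving out the deepest 5% of cells were added after seeing the data.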

Results

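Gene expression was measured in coronary artery endothelial cells, which line the arteries of the heart, after 14 days on a 4 kPa hydrogel or on tissue culture plates (TC), with or without TGF-β, a cytokine that drives endothelial cells toward a mesenchymal state. The question behind the series was how the stiffness of the substrate alters endothelial phenotype. Counts were analysed for 3 of the 4 libraries. The 4kPa library had a median of 26786 UMIs and 5605 genes per kept cell, the 4kPa+TGFB library 31702 UMIs and 5941 genes, and the TC library 20971 UMIs and 4835 genes. There was 1 library per condition and therefore no replicate error for any difference below; intervals cover counting error only, and "higher" and "lower" describe these libraries.

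All 3 libraries kept an endothelial profile. PECAM1 and CDH5, which encode junctional adhesion proteins of endothelium, stood at 657 CPM (95% interval 653 to 662) and 408 CPM (405 to 412) in 4kPa, at 618 CPM (614 to 623) and 416 CPM (413 to 420) in 4kPa+TGFB, and at 566 CPM (562 to 570) and 415 CPM (412 to 419) in TC. After thinning to 5000 UMIs, a UMI of PECAM1 or CDH5 was found in 97.6% of 4kPa cells, 95.05% of 4kPa+TGFB cells and 95.2% of TC cells (98.2%, 96.4% and 91.7% without thinning). Most markers of other cell types were scarce, apart from keratins. Of the fibroblast markers, only COL1A2 reached 5 CPM, at 7.94 CPM in TC. The leukocyte gene PTPRC was found in 0 of 4480, 3130 and 5085 thinned cells, and in 1 cell of 4kPa, 0 of 4kPa+TGFB and 4 of TC without thinning, while the leukocyte-list genes CD68 (16.8, 17.1 and 14.9 CPM) and LAPTM5 (23.8, 23.7 and 25.1 CPM) were measured in each library. Erythroid markers lay below 1 CPM in all 3 libraries. Keratins of the epithelial list were abundant: KRT7 stood at 544, 909.5 and 1216.5 CPM, KRT18 at 159, 209 and 304 CPM and KRT19 at 123, 166 and 159 CPM. EPCAM, an epithelial adhesion gene, stood at 0.0732, 0.0831 and 0.1 CPM.

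The first comparison, TC over 4kPa, addressed the substrate without TGF-β. A culture plate and a hydrogel differ in material as well as stiffness, and no stiffness value is given for TC. An effect of stiffness therefore cannot be told apart from other differences between the substrates. The genes furthest above 4kPa on TC included chemokines, some smooth-muscle cytoskeletal genes and KRT7. CXCL1, a neutrophil-attracting chemokine, was 2.75-fold higher (95% interval 2.66 to 2.83), at 110 CPM against 40.03 CPM. TAGLN, an actin-binding protein of smooth muscle, was 2.34-fold higher (2.29 to 2.39), at 209 CPM against 89.5 CPM. KRT7, an intermediate filament keratin, was 2.23-fold higher (2.22 to 2.25), at 1216.5 CPM against 544 CPM. CDH13, which encodes T-cadherin, was 2.11-fold lower (2.04 to 2.19), at 34.3 CPM against 72.5 CPM. Genes that lie between these extremes were mostly close: of 8678 genes with at least 10 CPM, 26 were at least 2-fold higher and 12 at least 2-fold lower, and log2 CPM of the libraries correlated with r = 0.989 across genes, which are not independent replicates. With median-of-ratios scaling, which shifts each log2 ratio by 0.085, the counts were 42 and 9.

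The other genes furthest above 4kPa were COL8A1, a short-chain collagen (2.17-fold), ANKRD1 (2.10-fold), IL1RL1, the receptor of interleukin 33 (2.07-fold), MGARP (2.02-fold), CCL2, a monocyte-attracting chemokine (1.99-fold), TPM2, a tropomyosin (1.99-fold), and IGFBP7 (1.97-fold). Those furthest below were BMPER, a secreted binder of bone morphogenetic proteins (1.97-fold lower), NDRG1 (1.91-fold), DUSP4 (1.86-fold), PMP22 (1.84-fold), C1orf21 (1.82-fold), ADAMTS18 (1.79-fold), TFPI2, a serine protease inhibitor (1.78-fold), HMOX1, the heme-degrading oxygenase (1.76-fold), and NDRG4 (1.75-fold). Below the 50 CPM limit the ends, chosen after their values were seen, were CPA4, 3.07-fold higher at 23.5 CPM, and NFATC2, at 2.88 CPM in TC against 16.3 CPM in 4kPa. In GRCh38, TAGLN (ENSG00000149591) spans 117199321 to 117204782 of chromosome 11, KRT7 (ENSG00000135480) 52232520 to 52252186 of chromosome 12, CXCL1 (ENSG00000163739) 73869393 to 73871242 of chromosome 4, and CDH13 (ENSG00000140945) 82626803 to 83800640 of chromosome 16, all annotated as protein-coding genes. The UMIs come from 3′-end libraries and were counted per gene.

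**Figure D1:**
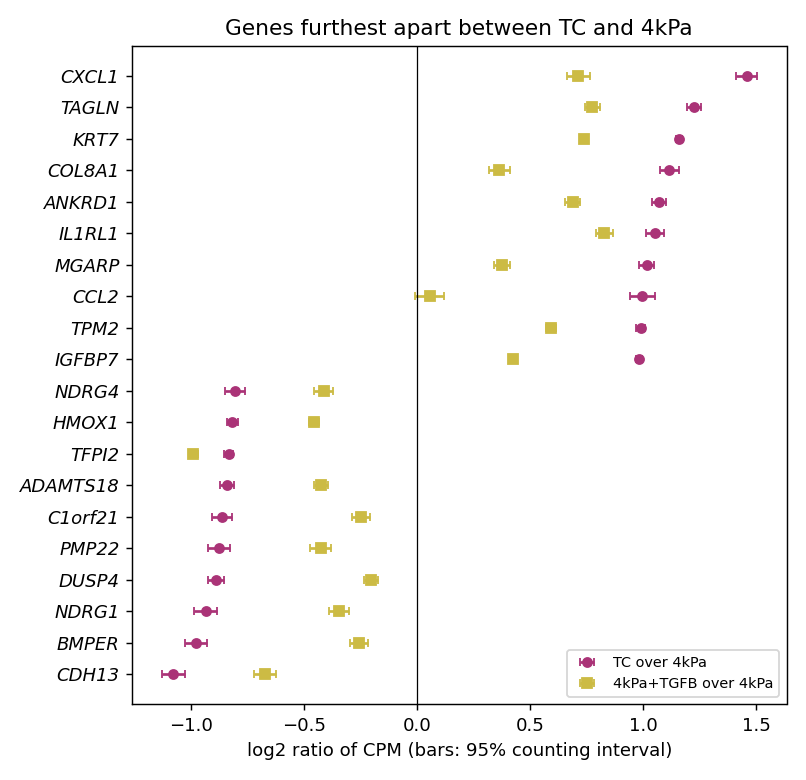
log2 ratio of CPM (x axis) for the 10 genes highest and the 10 lowest in TC over 4kPa (y axis); circles show TC over 4kPa, squares 4kPa+TGFB over 4kPa, and bars the 95% counting interval, each from 1 library per group. Squares lie on the same side of 0 as circles, with CCL2 at 1.04-fold and an interval that includes 1, and TFPI2 is the only gene whose square lies further from 0 than its circle.

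Of the contractile genes, 4 of 8 measured members were at least 1.5-fold higher on TC and 0 lower, with a median log2 ratio of 0.48 (percentile 100 among random lists). They were TAGLN, MYL9 (2.01-fold), TPM2 and TPM1 (1.58-fold). At 5000 UMIs per cell, cells with at least 5 TAGLN UMIs (a limit chosen after the values were seen) held most TAGLN UMIs (69.5% in 1.56% of 4kPa cells, 72.2% in 3.97% of TC cells). They were poor in the nuclear RNA MALAT1, with a median of 48.5 UMIs in TC against 100 in other cells. Over cells with at least 25 MALAT1 UMIs, mean TAGLN was 0.254 UMIs in 4kPa and 0.574 in TC. ACTA2, the smooth muscle actin most used to mark mesenchymal transition, was not among them: it stood at 14.2 CPM (13.6 to 14.8) in 4kPa and 13.6 CPM (12.9 to 14.2) in TC, a ratio of 0.956. CNN1 rested on 20 UMIs in 4kPa and 85 in TC. Of 16 measured fibrillar collagen and matrix genes, 6 were higher and 0 lower (median 0.32, percentile 100), among them COL8A1, TGFBI (2.03-fold), LOX, which cross-links collagen (1.52-fold), and BGN (1.51-fold). COL1A2, a member of this list, was 1.91-fold higher. It is also the only fibroblast marker that reached 5 CPM, so it is 1 gene counted in both lists and not separate evidence. COL3A1, also on both lists, was found in 1.63% of 4kPa cells and 1.40% of TC cells thinned to 5000 UMIs. Of 16 regulators and markers of mesenchymal transition, 9 reached 5 CPM, and the others were not compared. Among these 9 only CDH2, which encodes N-cadherin, passed 1.5-fold (1.63-fold higher). The transcription factor genes ZEB1 and ZEB2 had ratios of 0.72 and 0.725, and the list's median was −0.14 (percentile 12.9).

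Targets of the YAP and TAZ co-activators, which respond to stiffness, were higher in part. Of 19 measured members 5 were at least 1.5-fold higher and 0 lower, with a median of 0.13 (percentile 99.95): TGFB2 (2.86-fold), ANKRD1, CTGF (1.95-fold), CYR61 (1.93-fold) and IGFBP3 (1.51-fold). None of 26 actin cytoskeleton and focal adhesion genes passed 1.5-fold either way (median 0.035, and −0.0078 with each cell weighted equally). The inflammatory list had 5 of 11 members higher and 0 lower (median 0.49, percentile 100), with CXCL1, CCL2, CXCL8 (1.95-fold), CXCL2 and IL6, while ICAM1 had a ratio of 1.03. Of 16 interferon response genes 3 were higher and 0 lower (median 0.31, percentile 100): IFI6 (1.86-fold), BST2 (1.60-fold) and IFI44L (1.51-fold). Antigen presentation genes did not differ by 1.5-fold (0 of 8, median 0.010).

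Endothelial identity genes stayed close between the libraries. None of 25 was 1.5-fold apart, and their median log2 ratio was −0.10 (percentile 1.27), −0.016 with median-of-ratios scaling and −0.19 with each cell weighted equally. The receptor genes TEK (ratio 0.708) and KDR (0.722) and the sialomucin gene EMCN (0.742) were lowest, while PLVAP was highest (1.44). Of 24 TGF-β and BMP response genes, 4 were higher (TGFB2, TGFBI, CTGF and LTBP2, 1.66-fold) and HEY1 was lower, with a median of −0.041 (percentile 53.2), which turned to 0.044 with median-of-ratios scaling. TGFB2 and CTGF are also on the YAP and TAZ list and TGFBI on the matrix list, so these lists are not independent in any comparison. Of 15 flow-regulated and vasoprotective genes, KLF4, PTGS2, the inducible cyclooxygenase, and HMOX1 were lower and EDN1, the precursor of the vasoconstrictor endothelin, was 1.89-fold higher. The median of that list was −0.20 (percentile 0.22). Genes near coronary disease loci had a median of −0.19 (percentile 0.2), with EDN1 higher and PLPP3, a lipid phosphatase, 1.63-fold lower among 20 measured.

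All 20 G2/M genes were higher in TC by less than 1.5-fold (median 0.38, percentile 100), for instance CENPE and CCNB1 (1.41-fold). The 18 G1/S genes had a median of 0.18 (percentile 100), which turned to −0.20 in cells without UMIs of 6 cycling genes, a selection that depends on depth and on the cell cycle itself. A UMI of MKI67 or TOP2A, genes of dividing cells, was found in 13.1% of 4kPa cells (95% interval 12.1% to 14.1%), 16.2% of 4kPa+TGFB cells (14.9% to 17.5%) and 15.8% of TC cells (14.8% to 16.8%) at equal depth.

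**Figure D2:**
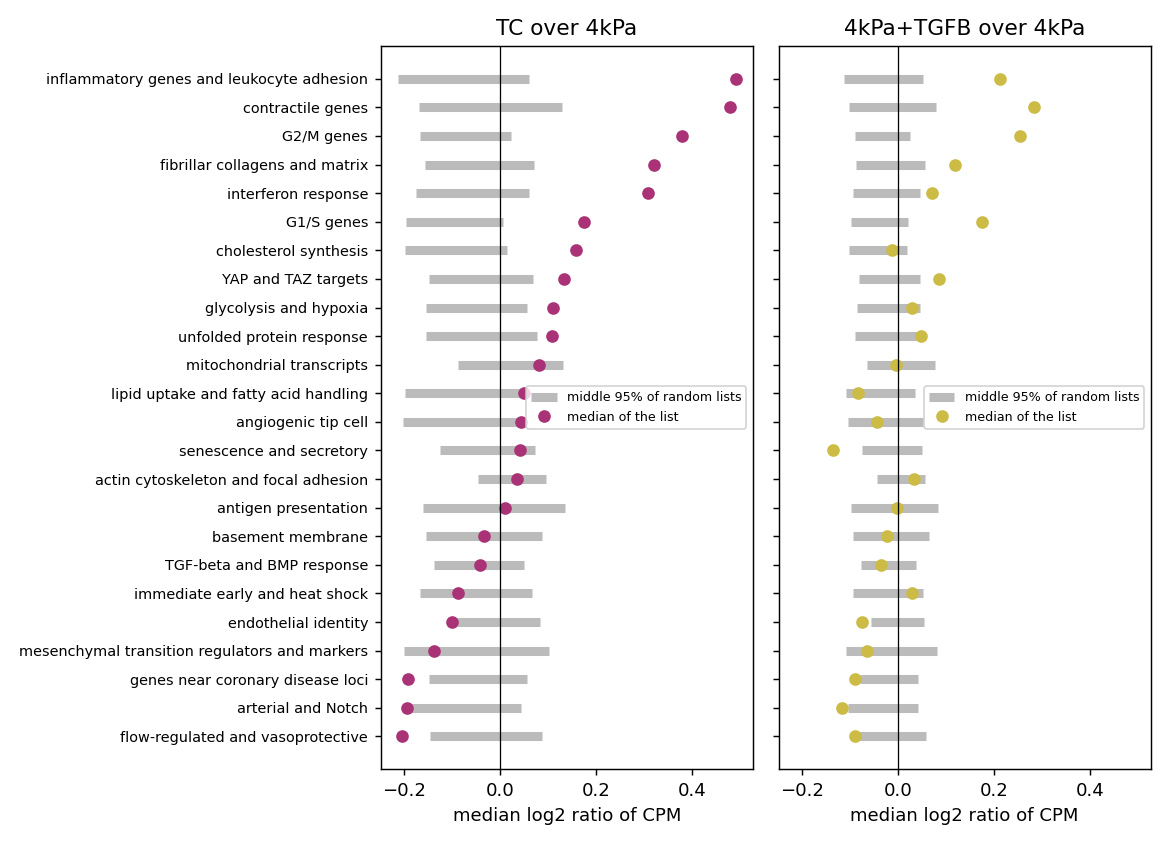
Median log2 ratio of CPM (x axis) of each gene list with at least 5 measured members (y axis), for TC over 4kPa (left panel) and 4kPa+TGFB over 4kPa (right panel), 1 library per group; grey bars span the middle 95% of 10000 random lists matched on CPM. Inflammatory and contractile genes lie furthest to the right for TC over 4kPa (0.49 and 0.48), and contractile and G2/M genes for 4kPa+TGFB over 4kPa (0.28 and 0.25).

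The second comparison, 4kPa+TGFB over 4kPa, addressed TGF-β on the soft gel. The differences were smaller. IL1RL1 was 1.78-fold higher (95% interval 1.73 to 1.83), TAGLN 1.71-fold (1.67 to 1.75), KRT7 1.67-fold (1.66 to 1.69), CXCL1 1.64-fold (1.58 to 1.70) and ANKRD1 1.61-fold (1.58 to 1.65). They were followed by GJA5, an arterial connexin (1.54-fold), TPM2 (1.51-fold), TNFRSF12A (1.47-fold), PTX3, a soluble pattern recognition protein (1.47-fold), and DKK1, a secreted WNT antagonist (1.45-fold). TFPI2 was 1.99-fold lower (1.96 to 2.02), CDH13 1.60-fold, EMCN 1.44-fold, JUP, which encodes plakoglobin of cell junctions, 1.38-fold, and HMOX1 1.37-fold. MGP, an inhibitor of calcification, was 1.35-fold lower at 1146 CPM against 1551 CPM. PMP22, ADAMTS18, IL33 and ADD3 were each 1.34-fold lower. Of 8657 genes, 0 were at least 2-fold higher and 1 was at least 2-fold lower, named after its value was seen: MMP10, a matrix metalloproteinase, at 8.65 CPM against 19.3 CPM.

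Known targets of TGF-β signalling went both ways in that comparison, so their median near 0 decides nothing. Whether a response was weak, had faded by day 14 or the library carries a wrong label was not tested, and this bears on every 4kPa+TGFB value. Of 24 TGF-β and BMP response genes, TGFB2 (1.72-fold) and TGFBI (1.58-fold) were higher and HEY1 was lower, and the median was −0.034 (percentile 30.8). CTGF had a ratio of 1.23 (1.21 to 1.24) and LTBP2 1.40. The feedback inhibitor genes SMAD7, SKIL and PMEPA1 had ratios of 0.987, 0.901 and 0.902. Of 8 contractile genes 2 were higher (TAGLN and TPM2; median 0.28, percentile 100), while ACTA2 stood at 15.7 CPM (14.96 to 16.4), a ratio of 1.10. Of 14 matrix genes 1 was higher, TGFBI, with a median of 0.12 (percentile 100), and COL1A2 had a ratio of 1.001. None of the 9 measured of 16 mesenchymal transition genes passed 1.5-fold (median −0.064), and CDH2 had a ratio of 1.21.

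Of 19 YAP and TAZ targets 2 were higher (TGFB2 and ANKRD1; median 0.087, percentile 99.85). In the inflammatory list CXCL1 alone of 10 members passed 1.5-fold, with a median of 0.21 (percentile 100), and CCL2 had a ratio of 1.04. Endothelial identity genes had 0 of 25 beyond 1.5-fold and a median of −0.074 (percentile 0.31). Of 14 arterial and Notch genes, GJA5 was higher and HEY1 and CXCR4 lower (median −0.12, percentile 1.06). PTGS2 was the only flow-regulated gene of 15 beyond 1.5-fold, at 17.5 CPM against 30.5 CPM, a ratio of 0.574 (median −0.089, percentile 1.69). G2/M and G1/S genes had medians of 0.25 and 0.18 (both at percentile 100) with 0 members beyond 1.5-fold, and the G1/S median turned to −0.097 in cells without cycling UMIs. In the other lists, NID2 was lower among 13 basement membrane genes, NID2 and CXCR4 among 12 tip cell genes and MMP10 among 19 senescence genes (median −0.13, percentile 0.04), and KRT7 was the only one of 4 epithelial genes beyond 1.5-fold. The actin, interferon, antigen presentation, venous, glycolysis, cholesterol, lipid, immediate early, protein folding, coronary loci, leukocyte and mitochondrial lists had 0 members beyond 1.5-fold.

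The third comparison, TC over 4kPa+TGFB, differs in both substrate and TGF-β, so it is descriptive only, and each of its libraries also enters another comparison. FABP4, a fatty acid binding protein, was 2.63-fold higher on TC at 48.7 CPM against 18.5 CPM, CD34 2.65-fold, APLN, the ligand of the apelin receptor, 2.09-fold, and CCNA1 2.17-fold. These were the 4 genes of 8570 that were at least 2-fold higher. The 4 that were at least 2-fold lower were FOSB, FOS, KLF4 and HS3ST1, of which FOSB and FOS are immediate early genes. The inflammatory list had 5 of 11 members higher and 0 lower (median 0.53, percentile 100), among them CCL2 (1.92-fold) and CXCL8 (1.74-fold). None of 8 contractile genes passed 1.5-fold (median 0.21), and the TGF-β and BMP response genes had a median of −0.038, or 0.017 with median-of-ratios scaling.

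Among the 210 genes at least 1.5-fold apart between TC and 4kPa, most lay on the same side of 4kPa in 4kPa+TGFB. Of 97 genes at least 1.5-fold higher in TC than in 4kPa, 91 were also higher in 4kPa+TGFB than in 4kPa, and of 113 lower ones 110 were also lower. The covariance of the log2 ratios over 8638 genes was 0.0239, against 0.000549 expected from counting error in the shared 4kPa library. A deviation of that 1 library from its condition would add to the first value and to these counts, and it cannot be measured here. With 0 higher genes and 1 lower gene at 2-fold in 4kPa+TGFB over 4kPa, the overlap of the 2-fold lists carries no information.

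TAGLN was found in a minority of cells in each library and KRT7 in most cells of TC and 4kPa+TGFB. At 5000 UMIs per cell, TAGLN was found in 11.1% of 4kPa cells (95% interval 10.2% to 12.1%), 18.7% of 4kPa+TGFB cells and 21.8% of TC cells (20.6% to 22.9%), and KRT7 in 49.0%, 65.0% and 67.3%. Without thinning the shares were 31.3%, 46.0% and 43.8% for TAGLN and 71.0%, 82.7% and 83.9% for KRT7. CTGF was found in 45.7%, 54.6% and 64.4% of thinned cells (KRT7 and CTGF were added after the sums were seen) and ACTA2 in 6.43%, 6.87% and 6.25%. Cells with both an endothelial UMI (PECAM1 or CDH5) and a contractile UMI (ACTA2, TAGLN or CNN1) made up 15.8%, 21.8% and 23.9%, where independent detection within each library would give 16.4%, 22.9% and 25.02%. No cell group that lacks these genes was at hand to measure free RNA, which may account for part of such shares at 1 UMI.

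**Figure D3:**
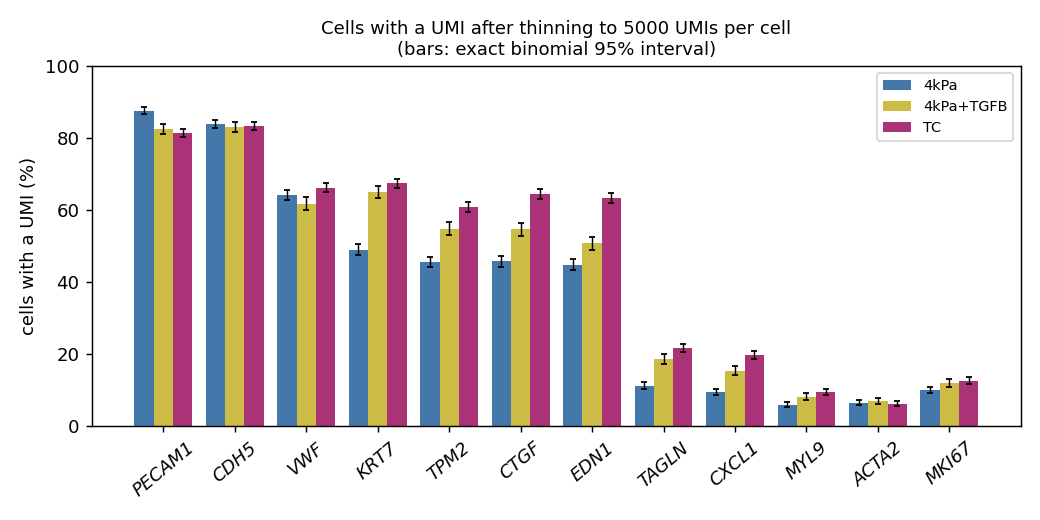
Percent of cells with at least 1 UMI of a gene (y axis) after drawing 5000 UMIs from each cell, for 12 genes (x axis) in the 3 libraries (colours); error bars are exact binomial 95% intervals over cells and cover counting error only. CDH5 is near 83% to 84% in each library, while TAGLN goes from 11.1% in 4kPa to 21.8% in TC.

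Clustering of all kept cells gave 11 clusters, each with cells of all 3 libraries. Clusters 1 and 3 were led by cell cycle genes such as CCNB1 and RRM2, cluster 4 by VCAN and GJA5, cluster 5 by PTGS2 and TFPI2, cluster 6 by FABP4 and AQP1, cluster 7 by TGFB2 and TAGLN, and cluster 8 by SULT1E1 and APLN. CDH5 ranged from 372 to 482 CPM over clusters 1 to 8. Cluster 9 (831 cells, median 3691 UMIs) was led by TAGLN, TPM2 and KRT7 among others and was low in CDH5 (27.7 CPM), PECAM1 (52.6 CPM) and the nuclear RNA MALAT1 (1132 CPM). Cluster 11 (224 cells) was led by TAGLN, MYL9 and TPM2, with CDH5 at 190 CPM and MALAT1 at 169 CPM, and cluster 10 (83 cells) had MALAT1 at 96493 CPM. Because several leading genes also differ between the libraries, cluster sizes were not compared as results, and the shares given below for cluster 7 are a description. Genes and clusters for the next values were chosen after the sums were seen, and clusters 9 to 11, in the first of which TAGLN had a ratio of 0.65 in TC over 4kPa, were left out. Within each of clusters 1 to 8, KRT7 was 1.53-fold to 2.46-fold higher in TC than in 4kPa, IGFBP7 1.47-fold to 2.30-fold, TPM2 1.33-fold to 1.82-fold, EDN1 1.46-fold to 2.63-fold and CTGF 1.40-fold to 2.34-fold. HMOX1, KLF4 and MMP1 were lower in TC in all 8. TAGLN (1.23-fold to 2.48-fold), CXCL1 (1.41-fold to 3.31-fold), ANKRD1, COL8A1, MYL9 and VWF were also higher in TC in all 8. Some genes did not keep their direction throughout. CDH13 and TFPI2 were lower in 7 of 8 and higher in cluster 2 (ratios of 1.32 and 1.12). IL1RL1 was higher in 7 of 8 with a ratio of 0.973 in cluster 4. In 4kPa+TGFB against 4kPa, KRT7 was higher in all 8 (1.13-fold to 1.85-fold) and TAGLN in 6 of 8. ANKRD1 and IGFBP7 were also higher in all 8, and CDH13, HMOX1 and TFPI2 lower in all 8. MYL9 was lower in 6 of 8 (ratios from 0.667 to 1.42). PECAM1 was higher in 5 of 8, although it was lower in the library sums (618 CPM against 657 CPM). In cluster 7 the ratios of TAGLN and IL1RL1 were 0.962 and 0.9998. Both are leading genes of that cluster, so grouping cells by them may itself draw these ratios toward 1. In cluster 4 the TAGLN ratio was 2.24. Cluster 7 held 6109 of 12221 TAGLN UMIs in 4kPa and 9724 of 18449 in 4kPa+TGFB. It held 4.49% of 4kPa cells and 9.84% of 4kPa+TGFB cells. How far the number of such cells accounts for the TAGLN and IL1RL1 ratios of the libraries was not tested.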

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

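All tests in this part were chosen after the pattern was seen. Barcodes too shallow to enter any comparison carried a signal: of those under 1000 UMIs, 157 of 389 in 4kPa, 60 of 439 in 4kPa+TGFB and 108 of 816 in TC were also listed in another library. Among kept cells the shares were 1.19%, 4.68% and 0.466%. In 113 barcodes with at least 20000 UMIs in 4kPa+TGFB and under 1000 in 4kPa, the shallow copy held a median of 0.608% of the deep copy's UMIs (10th to 90th percentile 0.572% to 0.658%).

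Chance use of 1 barcode in 2 libraries would leave a shallow copy no closer to its deep partner than to another deep barcode. The median correlation across genes, after centring each gene, was 0.149 with the partner and −0.00764 with another barcode for 4kPa and 4kPa+TGFB, 0.114 and 0.00437 for 4kPa+TGFB and TC, and 0.0518 and −0.0112 for 4kPa and TC. This argues against chance as the whole cause for barcodes with a deep partner. Of 100 barcodes shared by 4kPa and TC, 72 were under 1000 UMIs in both and had no deep partner among these, so their origin stays open. Reads that moved between libraries pooled on 1 flow cell (index hopping) are a candidate explanation for the former. Carry-over of material between droplet runs was not tested, and no biological explanation was tested, since the design gives none.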

How the results depend on the processing

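Leaving out cells under 5000 UMIs and leaving out the deepest 5% of cells were tried after seeing the data; the other settings were planned. All 57 ratios of named genes at least 1.5-fold apart stayed on the same side of 1 under all 10 settings of cells and scaling. Keeping doublet calls removed nothing and so tests nothing. Over 227 ratios of named genes, 2247 of 2267 alternative values kept their sign, and over 72 list medians 732 of 792 did. These totals include 227 and 72 values of the doublet setting, which kept their sign by construction. The 21 values of list medians and 13 of gene ratios marked as turned are given below, and most other changes of sign are not. Of 180 shares at 3000 or 10000 UMIs per cell 155 moved beyond their interval, as detection depends on depth. The cause of the other shifts was not tested unless stated. No replicate was left out, since there is 1 library per group.

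Counts of genes depended on the expression limit. With no CPM limit and at least 10 UMIs, where few counts scatter widely, 389 genes were at least 2-fold higher and 493 lower in TC over 4kPa, and 209 and 311 in 4kPa+TGFB over 4kPa. With at least 50 CPM, 7 were higher and 1 lower in TC over 4kPa and 0 lower in the other. Median-of-ratios scaling gave 42 higher in TC over 4kPa. In 4kPa+TGFB over 4kPa, cells without cycling UMIs gave 4 higher and 4 lower, equal weights 2 and 2, and leaving out the deepest 5% of cells 2 and 2. There, at most 10% mitochondrial UMIs gave 2 lower, as did leaving out mitochondrial and ribosomal protein genes. Leiden resolution 1 gave 18 clusters in place of 11.

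The contractile median of TC over 4kPa (0.48) was 0.56 with median-of-ratios scaling, 0.49 without mitochondrial and ribosomal protein genes, 0.44 with equal weights, 0.54 in cells without cycling UMIs, 0.37 without the deepest 5% and 0.66 for members of at least 20 CPM. That of 4kPa+TGFB over 4kPa (0.28) was 0.32 with median-of-ratios scaling, 0.33 in cells without cycling UMIs, 0.30 without the deepest cells and 0.34 for members of at least 20 CPM. The endothelial median of TC over 4kPa (−0.10) was −0.016 with median-of-ratios scaling, −0.19 with equal weights and −0.077 without the deepest cells. In 4kPa+TGFB over 4kPa (−0.074) it was −0.088 with limits at 3 median absolute deviations, −0.095 at 10% mitochondrial UMIs, −0.040 with median-of-ratios scaling, −0.089 with equal weights, −0.0398 in cells without cycling UMIs and −0.0893 without the deepest cells. The TGF-β and BMP response median of TC over 4kPa (−0.041) turned to 0.044 with median-of-ratios scaling and was −0.11 with equal weights, −0.095 in cells without cycling UMIs and −0.0098 for members of at least 20 CPM, where that of 4kPa+TGFB over 4kPa was 0.00225.

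Choosing cells without cycling UMIs depends on depth, which differs between the libraries, and lowers cell cycle genes partly by construction. In these cells the TC over 4kPa medians turned to −0.20 for G1/S genes, −0.019 for the actin list, −0.085 for lipid uptake, −0.025 for the senescence list and −0.0042 for mitochondrial transcripts. There the G1/S median of 4kPa+TGFB over 4kPa turned to −0.097, and in TC over 4kPa+TGFB basement membrane turned to −0.054 and actin to −0.018. Log2 ratios of TC over 4kPa turned to −0.042 for DUSP1, −0.30 for MCM4 and −0.0420 for TYMS. Those of 4kPa+TGFB over 4kPa turned to −0.19 for CENPE, 0.024 for HLA-E, −0.77 for HMMR, −0.090 for MCM4, −0.028 for SQLE, −0.067 for TYMS and 0.099 for VWF.

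With equal weights, the TC over 4kPa medians turned to −0.0078 for the actin list, −0.12 for senescence and −0.077 for mitochondrial transcripts, and log2 ratios to −0.079 for CDH5 and −0.063 for LAPTM5. VWF in 4kPa+TGFB over 4kPa turned to 0.02. In TC over 4kPa+TGFB, medians turned to −0.14 for basement membrane, −0.023 for actin, −0.020 for the tip cell list, −0.0065 for senescence and −0.0075 for mitochondrial transcripts. With median-of-ratios scaling the TGF-β and BMP response median of TC over 4kPa+TGFB turned to 0.017. In that comparison the immediate early median was 0.033 for members of at least 20 CPM, and without the deepest cells actin turned to −0.021 and G2/M to −0.0210.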

Other observations

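The gene lists in this part were fixed beforehand, and the other tests were chosen after the results were seen. TAGLN was concentrated in few cells. At 5000 UMIs per cell, cells with at least 5 TAGLN UMIs made up 1.56% of 4kPa (70 of 4480, 95% interval 1.22% to 1.97%), 3.07% of 4kPa+TGFB (96 of 3130, 2.49% to 3.73%) and 3.97% of TC (202 of 5085, 3.45% to 4.55%). They held 69.5%, 70.4% and 72.2% of all TAGLN UMIs. This limit is a range on a continuous measure, and 32, 44 and 85 cells lay at 4 or 5 UMIs. TAGLN-rich cells of TC had a median of 13 KRT7 UMIs against 2 in the other cells and 10 TPM2 UMIs against 1. A PECAM1 or CDH5 UMI was found in 71.4%, 67.7% and 70.8% of them, against 98.0%, 95.9% and 96.2% of the other cells. MKI67 or TOP2A was found in 8.57% (95% interval 3.21% to 17.7%), 7.29% (2.98% to 14.4%) and 5.45% (2.75% to 9.54%) against 13.1%, 16.5% and 16.2%. The 4kPa interval includes the share of the other cells, and these shares were not split by MALAT1. ACTA2 had a median of 0 in TAGLN-rich and in other cells.

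Many of these cells were poor in MALAT1, a nuclear RNA, with a median of 48.5 UMIs in TAGLN-rich cells of TC against 100 in the others. Among cells with at least 25 MALAT1 UMIs, TAGLN-rich cells made up 0.907% of 4kPa (0.639% to 1.25%), 1.66% of 4kPa+TGFB and 2.49% of TC (2.06% to 2.98%), and 81.1%, 84.4% and 85.8% of them had a PECAM1 or CDH5 UMI. Mean TAGLN over such cells was 0.254, 0.472 and 0.574 UMIs.

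Other gene lists were mixed or close between TC and 4kPa. None of 15 unfolded protein response genes passed 1.5-fold, with ratios of 1.47 for SDF2L1, 1.43 for HSP90B1 and 1.41 for HSPA5, while TRIB3 and DDIT4 stood at 0.775 and 0.756 (list median 0.11, percentile 99.4). Of 17 cholesterol synthesis genes 2 were higher, among them ACAT2 (1.55-fold), with a median of 0.16 (percentile 100). That median was −0.013 for 4kPa+TGFB over 4kPa. FABP4 (2.38-fold) was the only one of 14 lipid genes beyond 1.5-fold. Of 18 glycolysis and hypoxia genes NDRG1 and VEGFA were lower, and the rest lay within 1.5-fold (median 0.11). In the senescence and secretory list IGFBP7, PLAU (1.54-fold) and IGFBP3 were higher, and MMP1, interstitial collagenase, MMP10 and PLAT lower, with MMP1 at 840 CPM against 1400 CPM. Of 15 immediate early and heat shock genes FOSB, FOS and ZFP36 were lower (median −0.088). APLN (2.09-fold) was higher and NID2 lower among 12 tip cell genes, and NID2 was the only one of 13 basement membrane genes beyond 1.5-fold. GJA5 (1.62-fold) was higher and HEY1 lower among 14 arterial and Notch genes (median −0.19, percentile 2.43). PROX1 was the only one of 4 venous and lymphatic genes beyond 1.5-fold, at 8.23 CPM against 14.8 CPM, and KRT18 (1.91-fold) joined KRT7 among 4 epithelial genes. The 13 mitochondrial transcripts had a median of 0.081, and CD68 and LAPTM5, the leukocyte markers measured, had ratios of 0.886 and 1.05.

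The 4kPa+TGFB library lay between 4kPa and TC: of 210 genes at least 1.5-fold apart between those, 199 had an intermediate level, at a median position of 0.431 from 4kPa (0) to TC (1). These genes were picked for the distance between 4kPa and TC, so a library that varies independently would also tend to fall between them. Over 8697 genes, 38 lay outside both by at least 1.2-fold and beyond counting error. Barcodes with at least 20000 UMIs in 1 library and under 1000 in another left at most a median of 0.859% of their UMIs there (6 barcodes of TC and 4kPa). Such pairs were chosen for a small copy, so a large share could not appear. That value alone therefore decides nothing about index hopping. However, only 4.68% of kept 4kPa+TGFB cells were listed in any other library. Barcodes with at least 2000 UMIs in both 4kPa+TGFB and 4kPa numbered 7, and 6 in both 4kPa+TGFB and TC. Hopped UMIs reach a kept cell only under a barcode shared with another library. These values argue against index hopping as the source of most intermediate levels. The variance of log2 ratios left to 4kPa+TGFB if the cultures vary independently was −0.00549, but this value is negative whenever a library lies between the others, so it decides nothing. On a score of 50 genes higher and 50 lower in TC, the SD over cells was 43.0, against 46.8 for a mixture of 4kPa and TC cells (difference −3.85, −5.38 to −2.15 over resampled cells) and 42.5 for a population between them. That goes against a plain mixture, but the distribution lay within 0.0335 of the best mixture (share 0.54), and the score rests on genes picked for the pattern, so a mixture stays open. An effect of TGF-β, variation between cultures and a wrong label stay open too, because each condition had 1 library.

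Kept cells with under 5000 UMIs and under 2% mitochondrial UMIs made up 1.495% of 4kPa, 4.06% of 4kPa+TGFB and 7.29% of TC (407 cells, 0.985% of the library's UMIs). In TC their MALAT1 level was 0.0531 of that in cells with at least 5000 UMIs (0.0181 to 0.105 over resampled cells) and NEAT1, also nuclear, 0.0293, so fragments of cells without a nucleus are a candidate explanation. Of these 407 barcodes 0 were listed in another library, which allows up to 0.737% and argues against index hopping. In 4kPa the MALAT1 ratio was 0.619 (0.162 to 1.23) over 69 cells and in 4kPa+TGFB 0.401 over 137, with NEAT1 ratios of 0.218 and 0.0995, so the same explanation stays open there. Whether stiffness or the way cells were detached gave the higher share on TC was not tested.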
